A study of Mus musculus with 3 samples.

How the data were processed

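The series measured RNA in single cells of mouse small-intestinal organoids on the 10x Genomics platform, with 1 library each of wild-type (WT), Daam1/2-deleted (D1/2) and Rnf43/Znrf3-deleted (RZ) organoids. The authors deposited a raw gene-by-barcode matrix of UMI counts for each library, empty droplets included, over 32285 genes. Per the submitters' processing notes, Cell Ranger 6.1.1, Cell Ranger ARC 6.1.1, Signac 1.8.0, Seurat 4.1.0, MACS2 and the genome build mm10 were used. The notes do not say which tool made which file, and the matrix headers give the software version as Cell Ranger 4. Symbols and identifiers were taken from the deposited gene lists, and coordinates from the GENCODE M21 annotation of mm10. Second copies of the barcode and gene lists were byte-identical and were not used.

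Everything from the raw matrices on was computed for the present text with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with random seed 1. The matrices held 2106166 (WT), 1949653 (D1/2) and 1668863 (RZ) barcodes, of which 423527, 505791 and 481259 had 0 UMIs. A barcode was kept as a cell with at least the larger of 1000 UMIs and the 99th percentile of UMIs of the top 3000 barcodes divided by 10, at least 500 genes and at most 20% mitochondrial UMIs. The UMI minimum came to 7893, 9692 and 5903, and the limits on genes and mitochondrial share then removed 6, 17 and 27 barcodes. Doublets were sought with Scrublet in Scanpy, which marked 0, 2 and 2 barcodes in the 3 libraries. That is too few to be credible, so doublets were in effect not removed. The 5956, 4189 and 5409 cells kept hold 81.1%, 73.7% and 65.8% of the UMIs, with a median of 3801.5, 4376 and 3232 genes and 5.49%, 5.62% and 6.27% mitochondrial UMIs. Droplets with under 100 UMIs, taken as free RNA, hold 2910103, 2164753 and 1658260 UMIs.

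The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Each gene's UMIs were summed over the cells of a library and scaled to the library's summed UMIs in those cells as CPM. The 3 contrasts were D1/2 against WT, RZ against WT and D1/2 against RZ. Each library is the only one of its group, so no test between groups was run. Intervals are exact Poisson for sums, conditional binomial for ratios and Clopper-Pearson for shares, at 95%, and cover counting error only. For a count of 0 cells the upper limit given is 3 counts. UMI counts below 3 were raised to 3 for log2 ratios. With 3 UMIs as the floor, the lowest level that could be told from 0 was 0.0231 (WT), 0.0259 (D1/2) and 0.0353 (RZ) CPM.

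There were 30 gene lists, 12 of them cell-type markers. The Paneth list has 18 genes, of which 17 are among the genes measured. A list's median log2 ratio used members with at least 20 UMIs in both libraries together and needed at least 3 of them. It was ranked among 10000 random lists of the same size drawn from the same 20 expression bins. Some genes are in more than 1 list.

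For clustering, counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were picked by dispersion within each library, leaving out the fixed markers, Defa genes, mitochondrial and ribosomal protein genes, Xist, Tsix and Y-linked genes. Values were standardised and clipped at 10. A shared neighbour graph from 30 principal components and 15 neighbours was clustered with Leiden at resolution 1, all libraries together and without batch correction. A cluster was named "-like" after a cell type with at least 3 of its markers at least 2-fold above all other cells (with 5 CPM added to both), at 5 CPM or more and with a UMI in at least 20% of its cells. No other type could have as many markers among its 10 leading genes. Named classes were compared within when both libraries had at least 50 cells. Paneth-high cells (at least 5% of UMIs from the Paneth list) were counted after thinning each cell to 2000 UMIs, which left out 0 cells.

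The named genes are, for each contrast, the 10 with the highest and the 10 with the lowest ratio among genes with at least 50 CPM in the higher library, over all cells and again over the stem-like and proliferating-like clusters. Mitochondrial, ribosomal protein, haemoglobin and Y-linked genes, Xist and unnamed gene models were left out. The targeted genes, all Paneth and Wnt target genes and the 2 members of every other list with the largest ratio among those at 20 CPM or more were added. The largest of these are printed, and some genes are not reported here.

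The pipeline was tested on simulated data. Over 13886, 13458 and 13560 genes in the 3 simulated contrasts the median error of log2 ratios was 0.03, 0.04 and 0.04, and intervals held the true ratio for 95.6%, 96.1% and 95.3% of genes. Lists without a shift lay outside the central 95% of random lists in 5%, 5.5% and 5.5% of draws, and lists shifted by 0.5 did in 100%. These lists were drawn at random and carried counting noise only. Members of a real list may move together, so these rates are no guide to how often a real list lies outside. All 66 simulated Paneth-high cells were found, but they were made with a Paneth share well above the limit of 5%. The other simulated cells were made without Paneth UMIs. This check therefore says nothing about cells near the limit or about free RNA.

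Alternatives set beforehand numbered 18. They changed the cell filter (a fixed minimum of 2000 UMIs, a mitochondrial limit of 10%), doublet removal, the scaling (median-of-ratios size factors, leaving out mitochondrial and ribosomal protein genes), free RNA (10% of UMIs subtracted), the clustering (resolution 0.5 and 2, each library on its own, genes centred within library, markers kept), the Paneth-high limit (2% and 10%) and thinning (4000 UMIs, none), the Paneth list without Lyz1, the Wnt list without Rnf43 and Znrf3, and the UMI minimum of list members. After the data were seen 3 were added: leaving out Mmp7, leaving out the 5% of cells with the highest Scrublet scores, and the mean of each cell's CPM in place of summed UMIs. Size factors shifted the median gene by −0.08, −0.09 and 0.01 on the log2 scale in the 3 contrasts.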

Results

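Single-cell RNA libraries were made from mouse small-intestinal organoids of 3 genotypes, with 1 library per genotype. The wild-type (WT) organoids grew with R-spondin, a ligand that keeps Wnt receptors at the cell surface. The D1/2 organoids carried floxed Daam1 and Daam2, formin genes whose products bind Dishevelled, and the RZ organoids carried floxed Rnf43 and Znrf3, whose products are E3 ligases that clear Wnt receptors. Recombination was induced in both mutant lines through Vil-CreERT2, recombined organoids were selected by withdrawing R-spondin, and both lines then stayed without it. All organoids had spent 10 days in their maintenance medium. The libraries held 160373206 UMIs (WT), 156864240 UMIs (D1/2) and 129332462 UMIs (RZ). After filtering, 5956 WT, 4189 D1/2 and 5409 RZ cells remained, with a median of 17012, 21163 and 12193 UMIs per cell.

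With 1 library per genotype no test of a difference is possible, so the values below describe these libraries and genotype stands together with medium and organoid line. Levels are given as CPM, a gene's UMIs scaled to the summed UMIs of the same cells. Their ranges in brackets are exact 95% Poisson intervals, shares carry exact binomial (Clopper-Pearson) intervals, and both cover counting error only. For a share of 0 the limit of 3 counts is given instead. A fold against 0 UMIs was computed against a floor of 3 UMIs in that library. For a gene list, the median log2 ratio of its members was placed among the medians of 10000 random lists of genes of like expression, as a description of these libraries. Coordinates refer to mm10. Xist, the RNA of the inactive X chromosome, stood at 970 CPM in D1/2, 0.0615 in WT and 0.0470 in RZ, so the D1/2 line also differed in sex from the others.

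Transcripts of Daam1, Rnf43 and Znrf3 remained detectable in the libraries of their mutants. Daam1 (ENSMUSG00000034574, chromosome 12, 71831078-71992333) stood at 11.0 CPM (10.4-11.6) in the D1/2 library, against 13.1 (12.5-13.7) in WT and 14.6 (13.8-15.4) in RZ. Daam2 (ENSMUSG00000040260, chromosome 17, 49456022-49564343) gave 7 UMIs in WT, 2 in D1/2 and 2 in RZ, too few to compare. Rnf43 (ENSMUSG00000034177, chromosome 11, 87662722-87735539) was 1.27-fold (1.24-1.30) higher in the RZ library than in WT, at 148.0 against 116.5, and Znrf3 (ENSMUSG00000041961, chromosome 11, 5276324-5444847) was 1.77-fold (1.67-1.88) higher, at 29.7 against 16.8. Both Rnf43 and Znrf3 are also Wnt targets. The libraries count the 3' ends of transcripts and the labels do not give the deleted exons, so these levels do not show whether the genes were inactivated.

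The comparison of D1/2 with WT organoids addressed what loss of Daam1 and Daam2 did to Paneth cells, the granule-secreting cells of the crypt base, and to Wnt signalling. In the D1/2 library the transcripts of Paneth granule proteins were nearly absent. The Paneth list without Mmp7 summed to 0.493 CPM (0.373-0.639), against 209.4 (207.0-211.9) in WT, a level 425-fold (328-561) lower. Mmp7, which codes for the protease that activates alpha-defensins, went the other way and was 6.30-fold (6.25-6.36) higher. Markers of goblet, enteroendocrine and absorptive cells were lower as well, while Lcn2, Cp and Cxcl5 were far higher.

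Of the 12 Paneth genes with enough UMIs to compare, 11 were at least 2-fold lower in the D1/2 library and Mmp7 was higher. The list's median log2 ratio was −5.35, lower than that of all 10000 random lists. Defa24 (ENSMUSG00000064213, chromosome 8, 21734494-21735471), an alpha-defensin, stood at 110.4 CPM in WT and 0.0605 in D1/2, 1824-fold (885-4538) lower. Alpha-defensin genes are near-identical paralogs, so which of them each UMI came from is uncertain, but their sum went the same way, from 148.7 in WT to 0.0865 in D1/2. Itln1 (ENSMUSG00000038209, chromosome 1, 171518122-171535294), a lectin, was 242-fold (159-392) lower. Ang4, an antimicrobial ribonuclease, gave 1359 UMIs in WT and 1 in D1/2. Lysozyme, Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797-117292868), was already scarce in WT, with 103 UMIs against 14. Clps was at least 29.9-fold lower, with 101 UMIs against 0. Defa5, Mptx1 and Mptx2 had at most 2 UMIs in any library, and Pla2g2a was not among the genes measured.

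Mmp7 (ENSMUSG00000018623, chromosome 9, 7692090-7699585) reached 2548 CPM (2539-2558) in the D1/2 library, 404 (401-408) in WT and 1156 (1148-1163) in RZ. The 20 D1/2 cells with most held 2.97% of its UMIs. In droplets with under 100 UMIs it stood at 2092 CPM in D1/2, 342 in WT and 1067 in RZ, so free RNA can place Mmp7 in cells that do not express it, and the share of cells that do was not read. Because Mmp7 outweighs the other members, the summed Paneth list was higher in D1/2 than in WT (log2 ratio 2.05), a direction that reversed to −8.73 once Mmp7 was left out, a setting chosen after the values were seen.

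**Figure D1:**
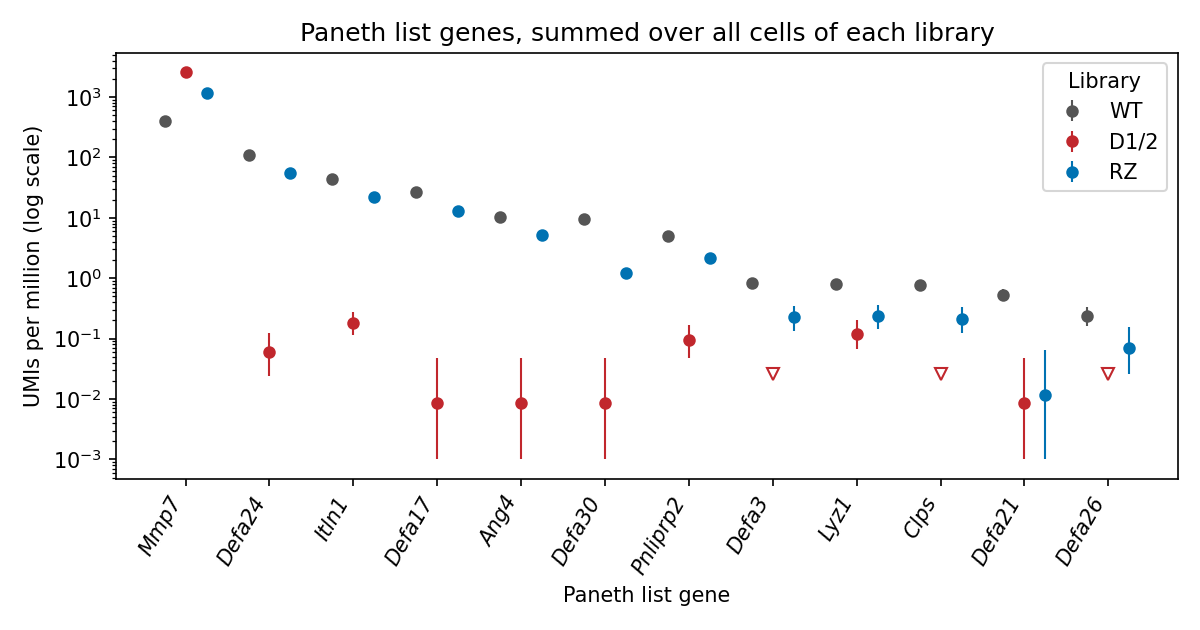
Levels of 12 Paneth genes in CPM (log axis) in the WT (grey), D1/2 (red) and RZ (blue) libraries, with exact 95% Poisson intervals as bars and open triangles at the floor of 3 UMIs where a library had 0. Mmp7 is highest in D1/2, while every other gene drawn is lowest there or, for Defa21, equally scarce in RZ by UMIs.

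Cells rich in Paneth transcripts were rare in every library. With each cell thinned to 2000 UMIs, at least 5% of them came from the Paneth list in 6 of 5956 WT cells (0.101%, 0.0370-0.219), in 0 of 4189 D1/2 cells, which allows up to 0.0716%, and in 2 of 5409 RZ cells (0.0370%, 0.00448-0.134). Between 2.5% and 10% lay 8 WT, 0 D1/2 and 4 RZ cells, so this limit marks a range and not a cell type. In droplets with under 100 UMIs, which hold free RNA, the Paneth list made up 0.0678% of WT, 0.209% of D1/2 and 0.124% of RZ UMIs. Barcodes of 100 to 1000 UMIs, below the minimum for a cell, held a higher level of the Paneth list without Mmp7 than the cells did in every library: 839 CPM (827-852) in WT, 7.57 (6.60-8.65) in D1/2 and 282 (277-288) in RZ. With Mmp7 left out and a limit of 0.5%, chosen after the values were seen, there were 34 WT cells (0.571%, 0.396-0.797), 0 D1/2 and 15 RZ cells (0.277%, 0.155-0.457). Within 2-fold of that limit lay 21 WT, 0 D1/2 and 14 RZ cells. The 20 cells with most held 69.1% of the WT and 73.0% of the RZ Paneth UMIs other than Mmp7. No cluster met the fixed rule for a Paneth-like name.

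Goblet, enteroendocrine and enterocyte markers were also lower in the D1/2 library. The goblet list had a median log2 ratio of −3.50, with 8 of 9 members at least 2-fold lower. Among them Tff3 (ENSMUSG00000024029, chromosome 17, 31125306-31129646), a trefoil peptide of mucus, was 189-fold (146-248) lower and Spink4 was 20.6-fold lower. At least 0.5% of thinned UMIs came from goblet markers in 58 WT cells (0.974%, 0.740-1.26) and in 0 D1/2 cells. Within 2-fold of that limit lay 54 WT cells, so it marks a range and not a cell type. The enteroendocrine median was −4.03, with 10 of 11 lower. The enterocyte median was −4.08, with 8 of 11 lower, among them the sodium-glucose transporter Slc5a1 (51.9 against 6.35 CPM). Other genes far lower in D1/2 were Prap1 (411-fold), Muc3 (122-fold), the calcium-binding S100g (60.5-fold), Lypd8 (58.9-fold), Adh1 (51.1-fold), Cldn15 (38.9-fold), Tm4sf4 (34.7-fold) and Adh6a (32.6-fold). The tuft list split: its median was −2.41 with 5 of 9 lower, yet its sum was higher, 33.3 against 8.54 CPM, through Dclk1 (25.8 against 2.13).

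Some genes were more than 20-fold higher in D1/2 than in WT. Wfdc2 (ENSMUSG00000017723, chromosome 2, 164562413-164568510) was 798-fold (671-956) higher, the copper carrier Cp (ENSMUSG00000003617, chromosome 3, 19957054-20009145) 665-fold (555-804) and the siderophore-binding Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633-32388252) 624-fold (568-688). Lactoferrin (Ltf, 314-fold), complement C3 (285-fold), Cxcl5 (89.9-fold), Wfdc18 (41.1-fold), Tnfaip2 (41.0-fold), Cxcl2 (27.4-fold) and Ccl2 (20.5-fold) followed. Of the Reg and MHC class II list 3 of 7 members were at least 2-fold higher and 2 lower (median 0.79), led by the C-type lectins Reg3b (ENSMUSG00000071356, chromosome 6, 78370657-78373466; 9.67-fold, 9.33-10.0) and Reg3g (101.9 against 16.8 CPM).

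Some stem cell markers were lower in D1/2. The stem list had a median of −0.51, below all random lists, with an interval of −3.50 to 0.43. Of its 11 members 3 were at least 2-fold lower, among them Smoc2 (11.3-fold) and Gkn3 (4.08-fold), Prom1 was higher (514 against 243 CPM) and 7 lay between, with Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311-115587780) at 126.2 against 147.5 CPM. The proliferation list had a median of 0.36, above 9994 random lists, with an interval of −0.09 to 0.50 and none of 14 members reaching a 2-fold difference. The fetal-like or regenerative list, genes of repairing epithelium, had a median of 0.74 (interval −0.01 to 1.30), above all random lists, with 4 of 13 members at least 2-fold higher and 0 lower. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118-104441050) was 7.92-fold (7.66-8.19) higher and Basp1 stood at 206 against 59.9 CPM.

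Over all cells, the Wnt/beta-catenin target list did not separate D1/2 from WT as a group. Its median was −0.03 over 20 genes, with 1 at least 2-fold higher (Notum, from 36 WT and 85 D1/2 UMIs) and 1 lower (Lef1, 10.4-fold). Axin2 (ENSMUSG00000000142, chromosome 11, 108920349-108950783), a feedback inhibitor of the pathway, stood at 47.5 CPM in D1/2 and 43.1 in WT, Sp5 at 43.8 and 27.9, and Tcf7 at 20.8 and 11.0. The medians of the Wnt ligand and receptor list (0.23) and the noncanonical Wnt and planar polarity list (0.26) lay within the central 95% of random lists, as did that of the Paneth regulators (−0.06).

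Other lists outside the central 95% of random lists were lower for interferon response (−1.03, 6 of 12 at least 2-fold lower; Ifit1 46.6 in WT and 10.8 in D1/2), secretory progenitors (−0.85, although their sum was higher, log2 ratio 0.29), fatty acid oxidation and PPAR targets (−0.35), BMP pathway (−0.29, where the mean of the members was 0.12) and EGFR and MAPK feedback (−0.19). Higher were the unfolded protein response (0.63; Hspa5 405 against 231 CPM), glycolysis and hypoxia (0.57; Bnip3 85.1 against 29.3), the Notch pathway (0.37; Hes1 929 against 632) and p53 targets (0.25). Inside it lay the YAP targets (0.16, although Ankrd1 was 6.22-fold higher), cholesterol synthesis (0.15), dissociation and immediate early genes (0.15), M cell markers (0.00, with a mean of 1.11) and the 3 detected immune markers (1.59, although their sum was lower, log2 ratio −0.70). In all, 7 of 27 lists lay above and 11 below. The mesenchymal, endothelial and erythroid lists had too few detected members for a median.

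**Figure D2:**
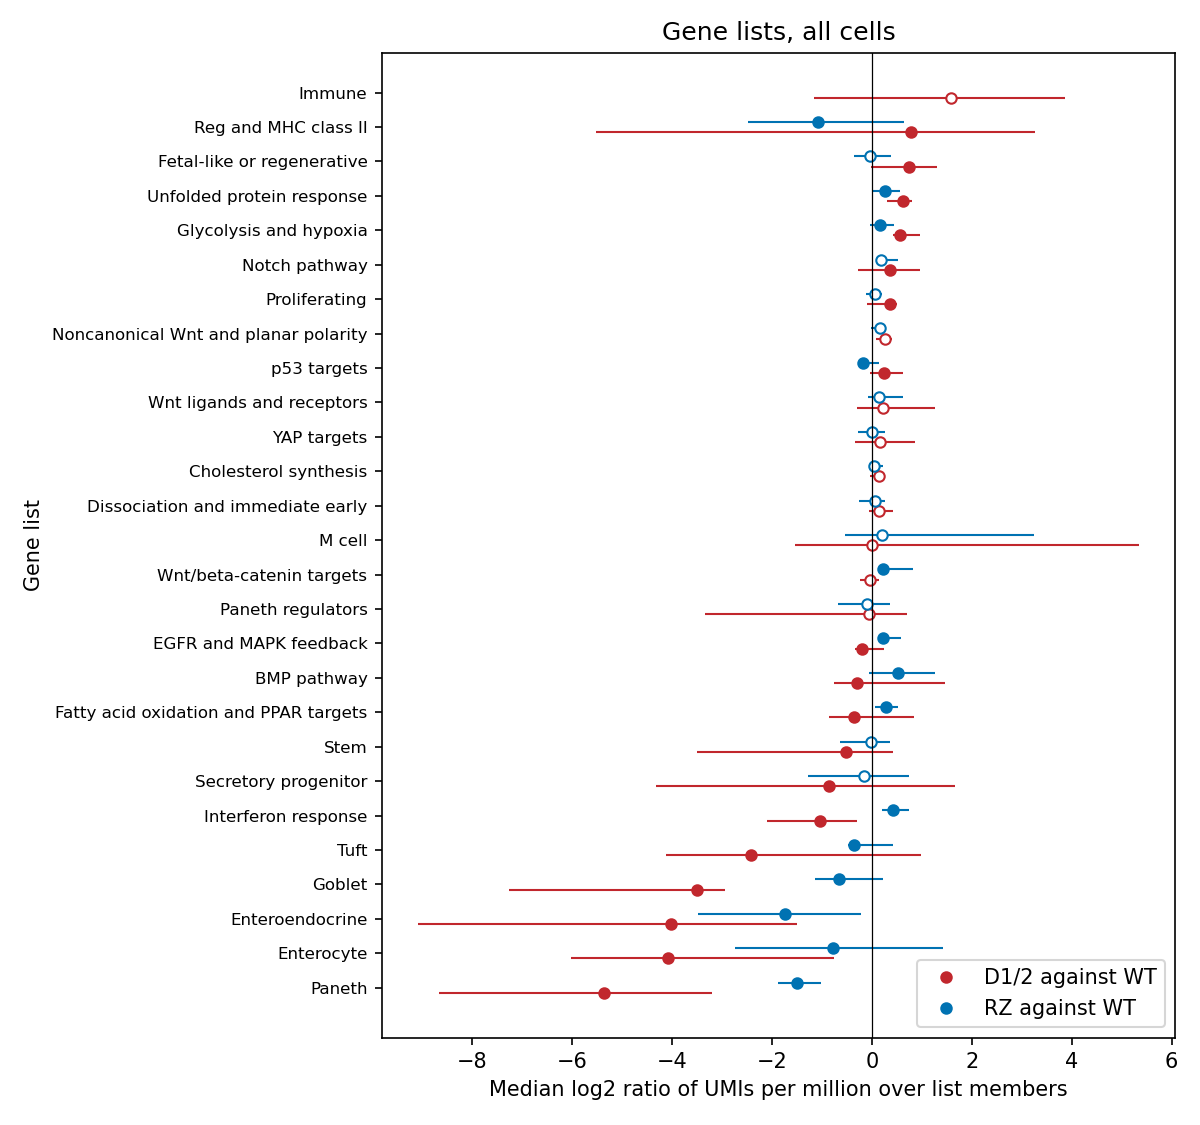
Median log2 ratio of CPM over the members of each gene list (horizontal axis) for D1/2 against WT (red) and RZ against WT (blue), with lines for the 95% interval of the median and filled points where the median lay outside the central 95% of 10000 random lists. For the M cell and immune lists, with few members, the line is the range of the members and covers the median at less than 95%. The Paneth, enteroendocrine, enterocyte and goblet medians lie below 0 in both comparisons, and further below in D1/2 than in RZ.

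The comparison of RZ with WT organoids addressed what loss of the Wnt receptor ligases did without R-spondin, in the medium the D1/2 organoids also had. Paneth transcripts were present but lower in the RZ library than in WT, and the median of the Wnt targets was slightly higher, with most of them within 2-fold. The Paneth list without Mmp7 stood at 99.7 CPM (97.6-101.9) in RZ, below WT by a log2 ratio of −1.07. Tnfrsf19, Nkd1, Prox1 and Lef1, Wnt targets, were more than 2-fold higher. Mmp7 was 2.86-fold (2.83-2.89) higher in RZ than in WT.

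Among Paneth genes 10 of 12 were at least 2-fold lower in RZ (median −1.49, below all random lists) and Mmp7 was higher. Defa24 stood at 55.0 CPM (2.01-fold lower, 1.94-2.08) and Itln1 at 22.5 (1.96-fold lower), while Lyz1 had 20 UMIs. In WT and RZ the 20 cells with most held 69.1% and 73.0% of the Paneth UMIs other than Mmp7. The difference between WT and RZ in these genes and their sum thus rests largely on few cells. The counting intervals do not cover which cells were sampled. The summed list was again higher through Mmp7 (log2 ratio 1.03) and lower without it. The enteroendocrine (−1.73), goblet (−0.65) and enterocyte (−0.77) medians were below all random lists, although the enterocyte sum was level with WT (log2 ratio 0.01) with 6 of 12 members at least 2-fold lower and 3 higher. Tff3 was 1.84-fold lower. The tuft median of −0.36, beside a higher sum (log2 ratio 0.41), turned to 0.05 when cells were kept from a fixed minimum of 2000 UMIs.

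The Wnt target list had a median of 0.22 in RZ, above 9906 random lists, and of 0.14 with median-of-ratios size factors, with 4 of 20 genes at least 2-fold higher and 0 lower. Tnfrsf19 (ENSMUSG00000060548, chromosome 14, 60963875-61046490) was 3.70-fold (3.39-4.05) higher, Nkd1 2.59-fold, Prox1 2.39-fold, Lef1 2.15-fold and Axin2 1.80-fold (1.74-1.87). Lgr5 did not differ in a stable direction: its log2 ratio was 0.04, but −0.03 with a mitochondrial limit of 10% and −0.05 with those size factors. The stem list median was −0.01 with a mean of 0.05, and Myc was lower in RZ, at 67.5 against 84.7 CPM.

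Outside the Wnt and cell-type lists, interferon-related genes were higher in RZ: the interferon list had a median of 0.43, above all random lists, Irf7 was 2.05-fold higher, and Ifi27l2a, outside that list, 7.51-fold (7.41-7.62). BMP pathway (0.53, interval −0.05 to 1.26, although its sum was lower, at 346 against 360 CPM), fatty acid oxidation and PPAR targets (0.29), unfolded protein response (0.26), EGFR and MAPK feedback (0.23; Dusp6 1.56-fold higher) and glycolysis and hypoxia (0.16) also lay above the central 95% of random lists. Reg and MHC class II (−1.08; Reg3b 5.60-fold lower) and p53 targets (−0.17) lay below. Among genes with at least 50 CPM in the higher library, the highest ratios, beside that of Ifi27l2a, were those of Wfdc2 (439-fold, 369-526), Tspan2 (14.6-fold), Zfp503 (8.07-fold), Sprr2a3 (7.66-fold), Baiap2l1 (5.86-fold) and Ly6c1 (4.04-fold). Genes with low ratios at that level included the aquaporin Aqp5 (12.9-fold lower), the metallothioneins Mt2 (5.93-fold) and Mt1 (3.20-fold), Pebp1 (3.50-fold) and Igfbp2 (3.41-fold).

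Set against each other, the D1/2 and RZ libraries shared the medium and differed in genotype, line and sex. Paneth granule transcripts were far lower in D1/2, 202-fold (156-267) below RZ as a sum without Mmp7. Mmp7 was 2.21-fold (2.19-2.22) higher in D1/2, so that with it the summed list was higher there (log2 ratio 1.02). Lcn2, Cp, C3, Ltf and Cxcl5 were high in D1/2 and not in RZ, whereas Wfdc2 and Zfp503 were high in both mutants. The median of the Wnt targets was lower in D1/2 than in RZ, although most of them differed by less than 2-fold.

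Defa24 was 908-fold (440-2260) and Itln1 124-fold (80.7-200.2) lower in D1/2 than in RZ, and Tff3 103-fold. Of the 8 Paneth genes compared 6 were at least 2-fold lower (median −6.25), and the enteroendocrine (−4.44), goblet (−3.03) and enterocyte (−2.54) medians were low too. The tuft median was −2.44 over 9 members, but the tuft sum was higher in D1/2 (33.3 against 11.3 CPM). Within the stem-like and proliferating-like clusters only 4 members had enough UMIs, and their median was 1.26. Lcn2 was 587-fold (525-660) higher in D1/2, C3 373-fold, Ltf 153-fold, Cxcl5 109-fold, Reg3b 54.2-fold and Ccl2 32.4-fold. Cp stood at 598 CPM in D1/2 and 0.0588 in RZ. Wfdc2 stood at 785 CPM in D1/2, 432 in RZ and 0.984 in WT, and Zfp503 at 71.7, 72.9 and 9.04. The fetal-like list was higher in D1/2 (median 0.84, 5 of 13 at least 2-fold higher and 1 lower; Spp1 16.0-fold higher), while interferon response (−1.51, 9 of 12 lower), fatty acid oxidation and PPAR targets (−0.71) and EGFR and MAPK feedback (−0.42) were lower.

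The Wnt target median between D1/2 and RZ was −0.24, below all but 44 random lists, with an interval of −0.71 to 0.29, and 5 of 20 genes were at least 2-fold lower and 1 higher. Lef1 was 22.4-fold lower, and Axin2 stood at 47.5 against 77.8 CPM and Tnfrsf19 at 5.39 against 20.1. Ccnd1 (log2 ratio −0.14) and Sox9 (−0.04) were slightly lower in D1/2 but changed sides, to 0.01 and 0.0021, when each cell's level was averaged instead of summing UMIs, a setting added after the values were seen.

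Clusters separated the libraries before they separated cell types: 10 of 13 clusters drew over 80% of their cells from 1 library, so a cluster of this kind may be that library and not a type. The fixed markers named 3 clusters proliferating-like and 1 stem-like, and left the rest unnamed. The proliferating-like clusters were cluster 4 (896 WT, 36 D1/2 and 463 RZ cells), cluster 6 (9, 1105 and 1) and cluster 7 (78, 3 and 1033). They held 16.5% (15.6-17.5) of WT, 27.3% (26.0-28.7) of D1/2 and 27.7% (26.5-28.9) of RZ cells. Neither difference from WT was stable in size, and that of RZ also changed direction. Across other settings the WT share ran from 7.99% at resolution 2 to 26.1% with genes centred within each library, where D1/2 had 28.3%. The RZ share was 13.4%, against 14.3% in WT, with a fixed minimum of 2000 UMIs. The stem-like cluster 10 held 1.29% of WT, 0.0477% of D1/2 and 13.1% of RZ cells, and with 90% of its cells from RZ this share was not compared between genotypes. Across other settings the WT stem-like share ran from 0 to 31.3%. Unnamed clusters held 82.2% of WT, 72.6% of D1/2 and 59.2% of RZ cells.

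Within the stem-like and proliferating-like clusters, where 1060 WT, 1146 D1/2 and 2208 RZ cells were summed, the median of the Wnt targets was highest in RZ and lowest in D1/2, although single targets differed in their order. Most of these cells came from cluster 4 in WT, cluster 6 in D1/2 and clusters 7 and 10 in RZ, so different clusters are being compared. The target list had a median of 0.33 for RZ against WT, −0.21 for D1/2 against WT and −0.63 for D1/2 against RZ, all outside the central 95% of random lists. Between D1/2 and WT the interval ran from −0.61 to 0.32, with 1 of 18 genes at least 2-fold higher, 1 lower and 16 between. Lgr5 was among the markers that named the stem-like cluster, so its level is not compared here, although the list holds it. In the proliferating-like clusters alone the medians were 0.41, −0.15 and −0.58, and in the stem-like cluster alone, with 77 WT cells, −0.25 for RZ against WT. Axin2 was 1.72-fold (1.61-1.83) higher in RZ than in WT, at 85.9 CPM, and lower in D1/2, at 41.4 CPM (log2 ratio −0.27 against WT). In the order WT, D1/2 and RZ, Znrf3 stood at 18.4, 12.7 and 33.0 CPM, Rnf43 at 112.9, 95.7 and 148.3, and Ephb2 at 65.7, 43.0 and 75.1. Tcf7 (11.6, 21.9 and 13.8), Sp5 (27.8, 49.8 and 38.0), Ccnd1 (549.7, 812 and 597), Cd44 (195, 243 and 213), Myc (75.8, 86.8 and 67.6) and Notum were highest in D1/2, Sox9 and Prox1 lowest in WT, and Ephb3 highest in WT.

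**Figure D3:**
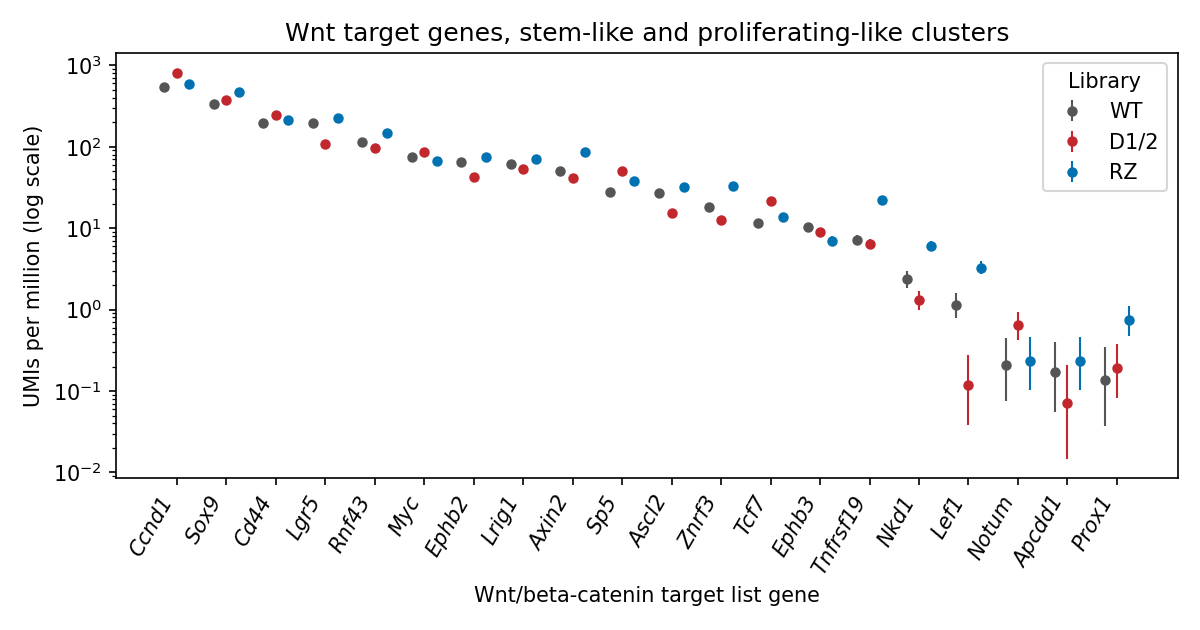
Levels of 20 Wnt/beta-catenin targets in CPM (log axis) over the stem-like and proliferating-like cells of the WT (grey), D1/2 (red) and RZ (blue) libraries, with exact 95% Poisson intervals as bars. Axin2, Znrf3, Rnf43 and Ephb2 are lowest in D1/2 and highest in RZ, while Tcf7, Sp5, Ccnd1, Cd44, Myc and Notum are highest in D1/2.

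Some of the differences seen over all cells were also found in these clusters. For D1/2 against WT the fetal-like median (1.42, 8 of 12 members at least 2-fold higher) was higher. The Paneth list is not read within these clusters, since free RNA of WT held it without Mmp7 at 336 CPM, above the level in WT cells. Mmp7, to which free RNA can add as well, was 7.10-fold higher there in D1/2 and 2.96-fold higher in RZ than in WT. Lcn2 stood at 1.37 CPM in WT, 1808 in D1/2 and 1.72 in RZ. The imprinted gene Peg3 (ENSMUSG00000002265, chromosome 7, 6703892-6730431) gave 1465 UMIs in WT, 0 in D1/2 and 485 in RZ. Against the floor of 3 UMIs it was 704-fold lower in D1/2 than in WT. The stem and proliferation lists, which the clusters were named by, are not compared within them.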

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

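All tests of explanations in this part were chosen after the result was seen.

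Droplets with under 100 UMIs lie outside the cells on which the ratios of genes and lists rest. Of 30 gene lists, 2 stood there at 20 CPM or more in D1/2 with the lower end of the interval more than 2-fold above the upper end in WT. The Paneth list stood at 2093 CPM (2033-2155) there, against 678 (648-708) in WT droplets and 2549 in D1/2 cells. Nearly all of it was Mmp7, at 2092 CPM. The Reg and MHC class II list stood at 369 CPM (344-396), against 68.4 (59.2-78.6) in WT droplets and 386 in D1/2 cells, led by Reg3b at 250.4 CPM and Reg3g at 94.2 CPM.

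The near absence of defensin and other Paneth secretory transcripts in the D1/2 library is the first pattern. Had Paneth cells lysed in the loaded suspension or been lost to the cell filter, their RNA would remain in the other droplets. But in droplets with under 100 UMIs the Paneth list without Mmp7 stood at 0.924 CPM (0.112-3.34, from 2 UMIs), against 336 (315-358, from 978 UMIs) in WT. In those with 100 to 1000 UMIs the list stood at 7.57 CPM against 839. Fewer UMIs in the D1/2 library do not account for it either, since its cells gave 57 such UMIs (43.2-73.9) where the WT level would have given 24218. The sex or line of the organoids cannot be told apart from the deletion: Xist stood at 970 CPM in D1/2 and 0.0615 in WT, and each line is 1 library. Loss of Paneth cells before loading, intact or lysed with their RNA removed, stays open beside the biological explanation that the deletion lowered these transcripts. So does the medium without R-spondin for the part that RZ organoids shared, or for more if the RZ deletion offset its effect. In that medium RZ organoids held the list without Mmp7 at 99.7 CPM (97.6-101.9), against 209.4 in WT and 0.493 in D1/2.

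Mmp7, a Paneth gene, was higher in D1/2 while the other Paneth genes were lower. RNA of Paneth cells spread through the suspension would have brought 696 CPM of Defa24, which stood at 0.0605 CPM (0.0243-0.125). A few cells with very high Mmp7 would have held most of it, but the 20 cells with most held 2.97% of the Mmp7 UMIs. The medium without R-spondin cannot be told apart from genotype for the part of the difference that RZ organoids in the same medium shared, 2.86-fold (2.83-2.89) above WT. The genotype, the line and its sex stay open for the rest. So does the medium, if the RZ deletion offset part of its effect.

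Lcn2, Cp, C3, Ltf and Cxcl5 were highest in the D1/2 library. Immune or stromal cells among the organoids would have brought their own abundant transcripts, but beside 2072 CPM of Lcn2 both lists together stood at 5.12 CPM (4.72-5.55), with the immune list lower than in WT (2.101 against 3.42 CPM) and the mesenchymal list higher (3.02 against 0.699, and 0.282 in RZ), mostly through Vim. As for a direct effect of sex, 0 of the 5 genes lie on X or Y, which leaves indirect effects open. The line of the organoids cannot be told apart from the deletion. D1/2 cells that clustered with the other libraries held 56.7 CPM of Lcn2 (49.3-65.0), against 2138 CPM in the rest, and cells with Xist made up both. Clustering on expression set these cells apart, so this contrast is in part built into the choice and cannot decide between line and deletion. A response to the deletion is the biological explanation and may hold, but 1 library of 1 line does not separate it from a property of that line. The medium without R-spondin was not separated either. RZ organoids in it were not high in these genes, but the RZ deletion may have offset its effect.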

How the results depend on the processing

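Leaving out Mmp7, leaving out the cells with the highest Scrublet scores and averaging each cell's CPM were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. Counted over all alternatives, 667 of 672 gene-list medians and 1658 of 1953 values of named genes stayed within the interval of their main value. So did 22 of 24 values of targeted genes, 25 of 27 Paneth-high shares, 11 of 30 Paneth list sums and 11 of 54 class shares. A change of direction was checked only where the main interval of a ratio excluded equality or the main list median lay outside the central 95% of random lists. Elsewhere a value could change sign and still be counted. The interval of a list median reflects the spread of its members and is often wide, so these counts do not compare between kinds of result. Of the 53 rerun list medians outside the central 95% of random lists, 50 over all cells and 3 of the Wnt targets within clusters, 53 stayed outside with doublets kept and with size factors, 52 with a fixed minimum of 2000 UMIs, with a mitochondrial limit of 10%, with free RNA subtracted and with the highest Scrublet scores left out, and 46 with no minimum of UMIs per gene. With the mean of each cell's CPM 47 of 50 did. Size factors shift a list and its random lists alike, so the place of a median among them could not change. Over all cells, keeping doublets added back only 2 D1/2 and 2 RZ barcodes, so little could change there. These 2 settings are thus no check of those medians over all cells. Other medians within clusters were not rerun. Those that came to lie inside were tuft for RZ against WT with a fixed minimum of 2000 UMIs, a mitochondrial limit of 10%, free RNA subtracted and no minimum of UMIs per gene, and Reg and MHC class II for D1/2 against WT without the highest Scrublet scores and with the mean of each cell's CPM. That mean did the same for enterocytes (RZ against WT) and proliferation (D1/2 against RZ). No minimum of UMIs per gene did so for tuft (D1/2 against WT and against RZ), secretory progenitors (D1/2 against WT), fatty acid oxidation and glycolysis (RZ against WT) and Notch (D1/2 against RZ). In 6 settings 2 to 4 others came to lie outside: Reg and MHC class II, YAP targets, M cell and secretory progenitor lists for D1/2 against RZ, Paneth regulators for RZ against WT and M cells for D1/2 against WT. No setting gave a Paneth-like cluster, so there is no Paneth-like share. The reversal without Mmp7 follows from leaving out the gene that makes up most of the sum. For all other values below the cause was not tested. Depth limits the D1/2 Paneth genes with 0 or 1 UMI and Daam2.

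The log2 ratio of the summed Paneth list is given in the order D1/2 against WT, RZ against WT and D1/2 against RZ where all moved. Without Mmp7 it reversed to −8.73, −1.07 and −7.66. It was 2.03, 1.00 and 1.03 with the highest 5% of Scrublet scores left out, 2.099, 1.05 and 1.05 with free RNA subtracted, and 1.86, 0.96 and 0.90 as the mean of each cell's CPM. For D1/2 against WT and RZ against WT it was 1.97 and 0.94 with size factors, and 2.00 and 0.97 without mitochondrial and ribosomal protein genes. A fixed minimum of 2000 UMIs gave 2.03 for D1/2 against WT and 1.00 for D1/2 against RZ, and a mitochondrial limit of 10% gave 1.04 for the latter. At a limit of 2% of UMIs the Paneth-high share was 0.269% in WT and 0.166% in RZ.

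For RZ against WT, the tuft median reversed to 0.055 with a fixed minimum of 2000 UMIs and moved to −0.75 with the mean of each cell's CPM. Lgr5 reversed to −0.028 with a mitochondrial limit of 10% and −0.054 with size factors. Size factors also moved the log2 ratios of Rnf43 to 0.26 and Znrf3 to 0.74, and the medians of the Wnt targets to 0.14, cholesterol synthesis to −0.052 and EGFR and MAPK feedback to 0.14. For D1/2 against RZ, Ccnd1 reversed to 0.0056 and Sox9 to 0.0021 with the mean of each cell's CPM.

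Class shares moved most. In WT, D1/2 and RZ, stem-like cells made up 18.4%, 0.389% and 14.97% with a fixed minimum of 2000 UMIs, 11.3%, 0.286% and 15.5% with doublets kept, 0%, 0% and 0% with the highest 5% of Scrublet scores left out, 31.3%, 0.716% and 20.1% at resolution 0.5, and 11.2%, 0.263% and 14.8% at resolution 2. With each library clustered on its own they made up 9.35%, 0% and 16.3%, with genes centred within each library 13.8%, 0.310% and 11.5%, and with markers and Defa genes kept 18.7%, 0.621% and 22.8%. A mitochondrial limit of 10% gave 20.7% in RZ. Proliferating-like cells made up 14.3%, 23.7% and 13.4% with a fixed minimum of 2000 UMIs and 13.3%, 25.9% and 14.2% with the highest 5% of Scrublet scores left out. In WT and RZ they made up 12.6% and 19.6% with a mitochondrial limit of 10%, 21.5% and 26.1% with doublets kept, 7.99% and 22.4% at resolution 2, 20.7% and 25.2% with each library on its own, and 26.1% and 29.1% with genes centred. In RZ they were 22.6% at resolution 0.5 and 24.3% with markers kept. With doublets kept the WT cells were the same 5956 as in the main setting, and only 2 D1/2 and 2 RZ barcodes were added. The WT shares still moved, from 1.29% to 11.3% stem-like and from 16.5% to 21.5% proliferating-like. Doublets among WT cells do not account for this, and the clusters and their names turned on a very small change of the cells.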

Other observations

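The lists named in the first paragraph, and the single genes in all of them, were chosen after their values were seen, so they are no independent evidence. A list of NF-kB targets and chemokines had a median log2 ratio of 1.41 for D1/2 against WT, with 15 of 18 members at least 2-fold higher, 0.38 for RZ against WT (mean −0.33, 1 member at least 2-fold higher and 2 lower) and 1.05 for D1/2 against RZ. Its feedback inhibitors Tnfaip3 (15.6 CPM in WT, 56.2 in D1/2 and 23.8 in RZ) and Nfkbia (164, 355 and 233) were highest in D1/2, as was the adhesion molecule Icam1 (0.838, 7.44 and 0.106). A list of intestinal transcription factors was lower in D1/2, with a median of −0.56 against WT (6 of 16 at least 2-fold lower, 2 higher) and −0.67 against RZ, and 0.10 for RZ against WT. Pdx1 stood at 15.1 CPM in WT, 0.458 in D1/2 and 24.6 in RZ, Hnf4a at 45.6, 15.2 and 40.7, and Hnf4g at 13.8, 3.25 and 12.8. Cdx1 gave 748, 1 and 18 UMIs. Klf4 (92.7, 236 and 178.5 CPM) was higher in D1/2 than in WT.

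Wfdc2 was high in both mutant libraries (0.984 CPM in WT, 785 in D1/2 and 432 in RZ). Its neighbours on chromosome 2 were not high in both: Sdc4 stood at 325, 319 and 331 CPM. Slpi was higher in D1/2 than in WT but not in RZ, at 0.0999, 9.18 and 0.0470 CPM. The imprinted gene Peg3 gave 3479 UMIs in WT, 0 in D1/2 (at least 1030-fold lower) and 573 in RZ over all cells, and Zim1, beside it, 156, 0 and 1.

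Of the 4189 D1/2 cells, 166 (3.96%, 3.39-4.60) lay in clusters made up mainly of WT or RZ cells, 67 of them in cluster 2 and 36 in cluster 4. At least 3 Xist UMIs were found in 160 of the 166 and at least 3 UMIs of Y-linked genes in 1, with both in none, so nearly all carried the sex marker of the D1/2 line. Clustering on expression set these cells apart, so differences from the other D1/2 cells are in part built into the choice. Compared with the other D1/2 cells, they held less Cp (28.4 against 616 CPM) and Mmp7 (779 against 2606 CPM) and more S100g (194 against 18.6), Lypd8 (87.5 against 2.62) and Hnf4a (38.7 against 14.4). Wfdc2 (434 against 796 CPM) and Zfp503 (58.6 against 72.2) were closer, and Peg3 gave 0 UMIs in both.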
